A study of Mus musculus with 15 samples.

How the data were processed

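Whole-transcriptome RNA sequencing was carried out on hippocampal neural precursor cells of 3 stable mouse lines, with 5 libraries per line. Per the labels' protocols, RNA was purified on columns with DNase digestion, libraries were made with the NEBNext Ultra RNA kit, which does not mark strand, and fragments were read as pairs of 150 bases on an Illumina NovaSeq. The authors' deposited table holds raw counts per gene, whole numbers that are not normalized, for 55416 Ensembl mouse gene identifiers and 15 libraries. STAR, edgeR and the build mm10 are named in the submitters' processing notes. The versions, the counting program, the strand setting and the annotation release are not given in the sources used here.

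The group and replicate number of each library were taken from its title. Gene symbols and coordinates come from GENCODE M21 on GRCm38, the assembly that mm10 also denotes. Of the 55416 identifiers 52083 received a symbol, and the 3333 without a symbol held at most 0.253% of the counts of a library. All identifiers name genes, and all entered the library totals. Totals were 53.7 to 69.6 M counts per library. Pairs of libraries within a line differed by more than sampling noise, with a chi-square of 5.54 to 53.8 per degree of freedom over genes with at least 20 counts, and each was counted as a separate sample. Labels give no sequencing batch or date.

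Counts were analysed in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by TMM, low genes were removed with filterByExpr, and 18244 genes remained of 35525 with any count. All 15 libraries were fitted together with a coefficient per line, and lines were compared with edgeR's quasi-likelihood test. P-values were adjusted by Benjamini and Hochberg over all genes tested, and genes with an adjusted p under 0.05 were called. A further count took only called genes with an absolute log2 fold change of at least 1. CPM values are divided by the TMM-scaled library totals, except where plain totals are named. Principal components were taken from log2 CPM of the tested genes. A gene's lines were said not to overlap when every library of one lay above every library of the other.

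In all, 28 gene lists with 387 entries, all matched to the table, were written before the data were examined, as were the tests of the comparisons, the rule for named genes and all alternatives except those named below as added later. They cover amino acid and one-carbon synthesis enzymes, amino acid transporters, aminoacyl-tRNA synthetases, integrated stress response effectors, endoplasmic reticulum chaperones, cytosolic heat shock proteins, immediate early and AP-1 genes, MAPK feedback genes, neural stem and precursor cell markers, proneural and early neuronal markers, axon growth and regeneration-associated genes, astrocyte markers, oligodendrocyte lineage markers, Notch pathway genes, S phase genes, G2 and M phase genes, p53 target genes, cholesterol synthesis genes, glycolysis genes, antioxidant and glutathione genes, autophagy and lysosome genes, interferon-stimulated genes, inflammatory signalling genes, mitochondrially encoded genes, microglia markers, endothelial markers, mural cell and fibroblast markers and ependymal markers. Some genes stand in more than 1 list. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in one direction, were run beside it. A list's members were also adjusted over the list alone.

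Named genes follow a rule: Atf3 and Atf4 in every comparison; the 6 largest rises and 6 largest falls per comparison among called genes with a mean log2 CPM of at least 2 and no overlap of the lines; up to 2 rising and 2 falling members per list with the smallest adjusted p; and 10 markers named whatever their result. Predicted genes and clone names were left out of the second part. The text uses a subset of the third part, and some genes under this rule are not reported here.

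The overlap of both responses was counted per direction. Chance was measured with 20 simulations of unchanged groups against the same controls, with the product of both lists' sizes, and with the 5 control libraries split between the comparisons in all 20 ways. The scripts were first tested on simulated counts with known changes for each comparison, over 18244 genes. For Atf3 against control 48, 58, 88 and 100% of genes changed 1.25-, 1.5-, 2- and 4-fold were recovered, for Atf4 against control 56, 76, 86 and 95.8%, and for Atf4 against Atf3 52, 64, 80 and 98%, with 5, 9 and 5 unchanged genes called. Each simulation changed at most 50 genes per fold and the glycolysis list, far fewer genes than were called in the real comparisons. Recovery and false calls in the real data may therefore differ from these values.

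The alternatives were DESeq2 1.42.0 and limma-voom in place of edgeR, RLE size factors in place of TMM, scaling without Atf3 and Atf4, no filter on low counts, a filter at 1 CPM in at least 5 libraries, the 10 libraries of a comparison alone, the replicate number as a block, each library left out in turn, a fold threshold, and other set tests. Leaving out control replicates 4 and 5 together, thinning all libraries to 1 depth, gaps between libraries on plain CPM, and the choice of genes for comparing sizes of change in both lines were added after seeing the data. Lists with under 5 tested members were described without a test.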

Results

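Gene expression was measured by RNA sequencing in adult neural precursor cells, the dividing cells of the hippocampus that can form neurons and glia, cultured from 6-week-old female mice. The cells were 3 stable lines made with the piggyBac transposon, each carrying a doxycycline-inducible (Tet-On) cassette and puromycin resistance. The cassette held the coding sequence of Atf3, that of Atf4, or neither (the control line). Both genes encode transcription factors of the basic leucine zipper family that are known to act in cellular stress responses. Differentiation was started by withdrawing EGF and FGF, doxycycline at 100 ng/ml was added to all 3 lines at that moment, and RNA was taken after 10 h. Each line was represented by 5 libraries, 15 in all. The sources used here do not say that replicates of a line were separate cultures, so p-values measure the spread between these samples, which may be technical. With 1 line per construct, a difference between lines cannot be separated from the transgene.

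Gene-level counts summed to 53.7 to 69.6 M per library, with means of 59.5 ± 5.41 M in the control line, 59.5 ± 3.48 M in the Atf3 line and 60.4 ± 6.32 M in the Atf4 line (SD, n = 5). The number of genes with any count was 26719 ± 318 in the control line, 24625 ± 232 in the Atf3 line and 25598 ± 274 in the Atf4 line. Of 18244 genes tested, the first principal component held 63.0% of the variance and the second 9.24%. Control libraries lay at -63.7 to -55.3 on the first component, Atf4 libraries at 1.11 to 27.1 and Atf3 libraries at 41.7 to 53.97. Atf4 replicate 5 was the Atf4 library closest to the Atf3 line, at 27.1, with the next at 14.3. Below, levels are normalized CPM (counts scaled to library size) as mean ± SD with n = 5 per line. A value followed by SE is a log2 fold change with an approximate standard error. This SE was the size of the change divided by the square root of the F statistic of the edgeR test. The library kit did not mark strand, and 27 of the 108 named genes share exon bases with another annotated gene. The largest parts shared with 1 other gene were 33.0% of exon bases in Phlda1, 31.8% in Hes5, 27.8% in Slc6a9, 24.3% in Miat and 22.1% in Dusp5, and the share of reads that came from the other gene was not measured.

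**Figure D1:**
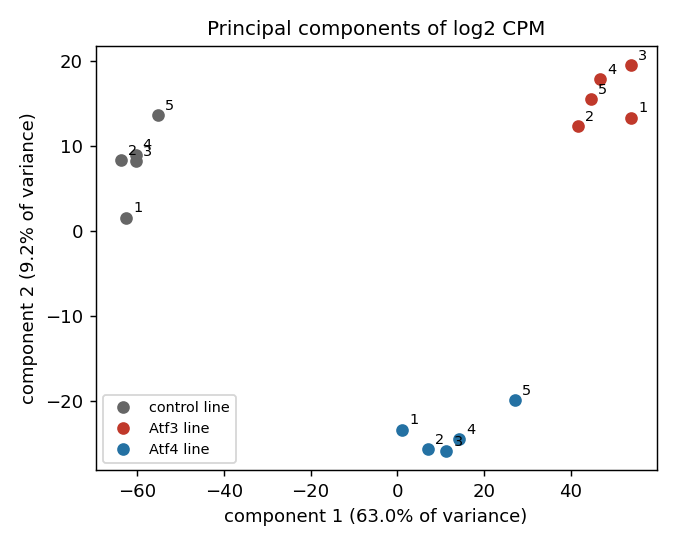
Principal components of log2 CPM over 18244 genes, with component 1 (63.0% of the variance) on the horizontal axis and component 2 (9.24%) on the vertical axis. Points are the 15 libraries, coloured by line and numbered by replicate; the Atf4 libraries lie at 1.11 to 27.1 on component 1, between the control libraries and the Atf3 libraries.

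The transgene-encoded mRNAs were examined first, since they check the labels. Atf3 (ENSMUSG00000026628; GRCm38 chromosome 1, 191170296 to 191218039, minus strand, a protein-coding gene) was at 5.02 ± 4.11 CPM in the control line, 1942 ± 119.6 CPM in the Atf3 line and 1.40 ± 0.306 CPM in the Atf4 line. It was 379-fold higher in the Atf3 line than in the control line (log2 fold change 8.57 ± 0.38 SE, edgeR quasi-likelihood test, adjusted p = 6.9e-13). In the Atf4 line Atf3 fell against control (-1.88 ± 0.43 SE, edgeR adjusted p = 9.1e-04). The control libraries ranged from 1.67 to 10.998 CPM of Atf3, and without control replicates 4 and 5, left out after seeing the data, these changes were 9.79 and -0.65. Atf4 (ENSMUSG00000042406; GRCm38 chromosome 15, 80255184 to 80257541, plus strand, a protein-coding gene) was at 83.2 ± 6.75 CPM in the control line, 250.4 ± 16.5 CPM in the Atf3 line and 153 ± 21.7 CPM in the Atf4 line. Its rise was 1.84-fold in the Atf4 line (0.88 ± 0.08 SE, edgeR adjusted p = 1.9e-08) and 3.01-fold in the Atf3 line (1.59 ± 0.08 SE, edgeR adjusted p = 3.4e-12). Atf4 was lower in the Atf4 line than in the Atf3 line, by 1.63-fold (-0.71 ± 0.08 SE, edgeR adjusted p = 1.9e-06). Counts per gene do not separate transgene from endogenous transcripts.

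**Figure D2:**
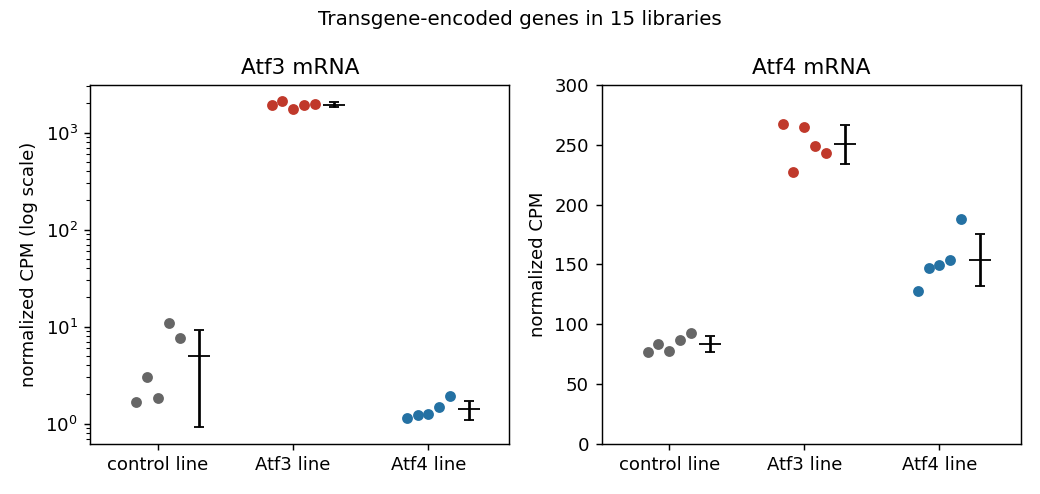
Normalized CPM of Atf3 (left, log scale) and Atf4 (right) in each of the 15 libraries, grouped by line; bars give the mean and SD of 5 libraries. Atf3 stands at 1942 ± 119.6 CPM in the Atf3 line, and Atf4 at 250.4 ± 16.5 CPM in the Atf3 line against 153 ± 21.7 CPM in the Atf4 line.

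The Atf3 line was compared with the control line to find the transcriptional changes that accompany Atf3 overexpression in differentiating precursor cells. All 16 genes of the fixed S phase list and all 16 aminoacyl-tRNA synthetases were higher in the Atf3 line, while all 11 tested oligodendrocyte lineage markers were lower. The neuronal tubulin Tubb3 fell from 85.1 ± 2.06 to 15.7 ± 1.97 CPM and the astrocyte filament gene Gfap from 134 ± 9.66 to 56.4 ± 2.65 CPM. The largest rises among the abundant genes, besides Atf3, included those of Apln, encoding the peptide hormone apelin (6.20 ± 0.579 to 124 ± 18.8 CPM), and Mthfd2, a mitochondrial enzyme of folate metabolism (7.75 ± 0.542 to 117 ± 10.5). They also included Cdc6, which loads the replicative helicase (1.61 ± 0.322 to 22.8 ± 1.58), and the cell cycle gene Ccnd2, cyclin D2 (28.3 ± 2.09 to 367 ± 50.5). Olfr618 rose as well (1.65 ± 0.173 to 29.5 ± 2.57), but it belongs to the olfactory receptor family, whose members share sequence, and its count is uncertain. Under the rule for named genes, the largest falls included that of the long noncoding RNA Miat (49.9 ± 4.49 to 0.791 ± 0.207 CPM). They also included those of Scg2, encoding the secretory granule protein secretogranin II (41.9 ± 4.50 to 1.25 ± 0.208), and the kinase gene Camk2a (52.4 ± 2.69 to 3.76 ± 0.662). Further large falls were those of the lipid droplet protein gene Plin3, the ubiquitin ligase gene Fbxo32 and the axon guidance gene Draxin (199 ± 11.96 to 18.8 ± 6.07). Each of these changes had an edgeR adjusted p of at most 4.5e-10.

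Genes of amino acid supply and of the integrated stress response, the program that cells start when amino acids run short or proteins misfold, were mostly higher in the Atf3 line. In the list of amino acid and one-carbon synthesis enzymes 13 of 14 rose and 1 fell (camera adjusted p = 1.1e-11, adjusted p = 0.0585 with an estimated correlation). Asns, asparagine synthetase, rose by 2.01 ± 0.07 SE and the serine synthesis gene Psat1 by 1.04 ± 0.03 SE on the log2 scale, whereas Gpt2, an alanine aminotransferase, fell (-0.46 ± 0.05 SE). Of the amino acid transporters 10 of 12 rose and 2 fell (camera adjusted p = 3.6e-04, adjusted p = 0.282 with an estimated correlation). The glycine transporter gene Slc6a9 rose (1.85 ± 0.08 SE) and the glutamine transporter gene Slc38a1 fell (-1.46 ± 0.14 SE). All 16 aminoacyl-tRNA synthetases rose, with a median log2 fold change of 1.35 (camera adjusted p = 1.3e-15, adjusted p = 0.133 with an estimated correlation). Vars rose by 1.91 ± 0.08 SE and Gars by 1.65 ± 0.07 SE. Among 16 tested effectors of the integrated stress response 13 rose, 2 fell and 1 was not called (camera adjusted p = 5.2e-06, adjusted p = 0.159 with an estimated correlation). The pseudokinase gene Trib3 rose from 0.783 ± 0.115 to 11.8 ± 2.24 CPM, and the translation repressor gene Eif4ebp1 by 1.99 ± 0.09 SE. The transcription factor gene Atf5 rose by 1.10 ± 0.05 SE and Ddit3, encoding CHOP, by 0.53 ± 0.07 SE. Ddit4, an inhibitor of mTORC1 signalling, fell (-0.60 ± 0.10 SE). Endoplasmic reticulum chaperones rose in 15 of 18 cases and fell in 1, with a median of only 0.33 (camera adjusted p = 0.00106, adjusted p = 0.165 with an estimated correlation). Manf rose by 0.72 ± 0.04 SE. Of 12 cytosolic heat shock proteins 8 rose and 3 fell (camera adjusted p = 0.00550, adjusted p = 0.0585 with an estimated correlation). The member with the smallest adjusted p was Hspd1 (1.34 ± 0.05 SE), whose product folds proteins in mitochondria and not in the cytosol.

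Most listed cell cycle, sterol and antioxidant genes were higher too. The S phase list had a median log2 fold change of 2.00 (camera adjusted p = 6.9e-34, adjusted p = 0.0288 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose from 39.1 ± 4.31 to 169 ± 7.34 CPM and the helicase gene Mcm6 from 50.3 ± 3.76 to 207 ± 9.95 CPM. Of the 16 G2 and M phase genes 13 rose and 3 fell (camera adjusted p = 0.00550, adjusted p = 0.415 with an estimated correlation). Aurkb had a log2 fold change of 1.06 ± 0.06 SE and Cenpf of -0.39 ± 0.10 SE. The proliferation marker Mki67 fell slightly (-0.26 ± 0.09 SE, edgeR adjusted p = 0.0208), a call that ended without Atf3 replicate 1, 2 or 4 (edgeR adjusted p = 0.0688, 0.0564 and 0.0557; 0.00625 to 0.0688 over all alternatives). All 17 cholesterol synthesis genes rose, with a median of 1.27 (camera adjusted p = 3.5e-09, adjusted p = 0.235 with an estimated correlation). Sqle rose by 1.26 ± 0.05 SE. Antioxidant and glutathione genes rose in 11 of 12 cases (camera adjusted p = 2.5e-06, adjusted p = 0.0288 with an estimated correlation). Among them were Gsr, glutathione reductase (1.14 ± 0.04 SE), and Gclm, a subunit of the enzyme that starts glutathione synthesis (0.69 ± 0.03 SE). Feedback genes of MAPK signalling, which rise when the pathway is active, rose in 10 of 12 cases and fell in 2 (camera adjusted p = 0.00259, adjusted p = 0.311 with an estimated correlation). Etv4 and Etv5 rose (2.23 ± 0.10 SE and 1.42 ± 0.06 SE) and Phlda1 fell (-1.29 ± 0.11 SE). Of the 12 glycolysis genes 9 rose and 1 fell (camera adjusted p = 0.00259, adjusted p = 0.248 with an estimated correlation). Ldha rose (1.32 ± 0.04 SE) and Pfkl fell (-0.70 ± 0.04 SE). The p53 target list had 10 of 13 members higher and 3 lower (camera adjusted p = 6.6e-04, adjusted p = 0.0585 with an estimated correlation). The cell cycle inhibitor Cdkn1a had a log2 fold change of 0.98 ± 0.04 SE and the antiproliferative gene Btg2 of -1.61 ± 0.17 SE.

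Oligodendrocyte lineage markers were lower in the Atf3 line. The 11 markers had a median of -1.53 (camera adjusted p = 7.7e-05, adjusted p = 0.159 with an estimated correlation). The oligodendrocyte precursor marker Cspg4 had a log2 fold change of -1.21 ± 0.07 SE. Of 19 proneural and early neuronal markers 6 rose and 10 fell (camera adjusted p = 0.0413, adjusted p = 0.194 with an estimated correlation). The transcription factor gene Myt1 fell by 3.09 and Tubb3 by 2.44 on the log2 scale. Dcx, a marker of young neurons, fell from 1.07 ± 0.112 to 0.553 ± 0.129 CPM. Of 13 Notch pathway genes 2 rose and 9 fell (camera adjusted p = 0.0432, adjusted p = 0.194 with an estimated correlation). The ligand gene Jag1 rose (0.84 ± 0.07 SE) and the target gene Hes5 fell (-3.44 ± 0.25 SE). Interferon-stimulated genes fell in 6 of 11 cases (camera adjusted p = 0.0432, adjusted p = 0.404 with an estimated correlation). Rsad2 fell by 2.39 and Irf7 by 2.09 on the log2 scale. Irf7 was low, at 2.52 to 2.78 CPM in the control libraries. Low genes tended to fall, with medians of -0.41 under 1 CPM, -0.17 at 1 to 10 CPM and 0.12 at 10 CPM or more. Whether the interferon list follows this trend was not tested. The list calls of the neuronal, Notch and interferon groups ended without control replicate 5 (camera adjusted p = 0.0512, 0.0615 and 0.0512), and those of the Notch and interferon lists without Atf3 replicate 5 (both 0.0535). The call of the interferon list also ended without Atf3 replicate 4 (0.0544), and that of the neuronal list with no filter on low counts (0.194). All 3 also ended without control replicates 4 and 5, left out after seeing the data (camera adjusted p = 0.0510, 0.0653 and 0.0640). Over all alternatives tested with camera, the adjusted p was 0.0117 to 0.194 for the neuronal list, 0.0165 to 0.194 for the Notch list and 0.0161 to 0.404 for the interferon list.

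The remaining lists did not pass the camera test against control (camera adjusted p-values in brackets). Of 16 neural stem and precursor cell markers 6 rose and 6 fell (camera adjusted p = 0.898). The radial glia gene Fabp7 and the filament gene Nes rose (1.18 ± 0.05 SE and 0.62 ± 0.07 SE), Id4 fell (-1.97 ± 0.14 SE), and Sox2 was at 228 ± 7.51 and 224 ± 13.3 CPM (edgeR adjusted p = 0.614). Of 11 astrocyte markers 3 rose and 5 fell (0.261), with Gfap at -1.25 ± 0.06 SE and the lipoprotein gene Apoe at -2.28 ± 0.12 SE. Among 17 immediate early and AP-1 genes, which respond to stimulation within minutes, 2 rose and 8 fell (0.508), but 5 to 11 fell over the alternatives. Without control replicates 4 and 5, left out after seeing the data, 5 fell, and the list median was -0.01 in place of -0.51. Batf3 and Myc rose (2.66 ± 0.23 SE and 0.96 ± 0.20 SE), and Fosl2 and Nr4a1 fell (-1.08 ± 0.18 SE and -3.05 ± 0.46 SE, but -0.68 and -1.80 without those 2 control libraries). The other counts were 3 rising and 7 falling of 13 autophagy and lysosome genes (0.0840, but 0.0446 with the filter at 1 CPM and 0.0487 without control replicate 4, and 0.0446 to 0.580 over all camera tests) and 4 and 2 of 10 axon growth genes (0.859). They were 4 and 3 of 7 inflammatory signalling genes (0.776) and 3 and 2 of 13 mitochondrially encoded genes (0.859). The mitochondrial share of counts was 4.07 ± 0.0611% in the control line and 3.72 ± 0.281% in the Atf3 line, where Atf3 replicate 4 stood at 3.23%. Here and below this share is of plain totals, whereas fold changes use TMM-scaled totals. Among markers of cells that a precursor culture might also hold, 2 rose and 2 fell of 5 endothelial markers (0.319), with Kdr at 44.3 ± 1.74 and 10.1 ± 1.29 CPM. Further, 2 rose and 3 fell of 5 ependymal markers (0.494), and 1 rose and 1 fell of 2 tested microglia markers. Of 3 tested mural cell and fibroblast markers 1 fell. Median, mean and test differed in sign for the precursor list (median -0.0021, mean -0.18, camera upward) and the axon growth list (-0.08, 0.13, upward). They also differed for the endothelial list (0.13, -0.09, downward) and the mitochondrially encoded list, whose median and mean lay at or just above 0 with a downward test. The endothelial median was -0.0579 without control replicate 5 and 0.378 without Atf3 replicate 3. Counts adjusted over the list alone were identical for all 28 lists except the immediate early genes (2 rose, 7 fell) and the astrocyte markers (3 rose, 6 fell).

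In all, 6721 genes were higher and 6630 lower in the Atf3 line, 13351 of the 18244 tested (73.2%; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p under 0.05). With a change of at least 2-fold 1299 were higher and 1891 lower, but 672 and 313 among genes at a mean of 10 CPM or more. In 11078 genes every library of one line lay above every library of the other (60.7%, against 0.79% by chance). Of the 26 lists tested 17 passed with the preset correlation, and the S phase and antioxidant lists passed with an estimated one. A difference of this breadth between single lines includes many small changes, since the median size among the called genes was 0.55 on the log2 scale. TMM and RLE scaling both centre the typical gene, and the median log2 fold change over all tested genes was -0.017. A shift of most genes at once would thus not be seen, and the near-equal split of higher and lower genes follows in part from the scaling.

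The Atf4 line was compared with the control line to find the changes that accompany Atf4 overexpression. The same 16 S phase genes and 16 aminoacyl-tRNA synthetases were higher in the Atf4 line, and 14 of 17 immediate early and AP-1 genes were lower. The immediate early gene Fos was at 135 ± 107 CPM in the control line and 9.26 ± 2.30 CPM in the Atf4 line. The largest rises among abundant genes were those of Cdc6 (1.61 ± 0.322 to 19.8 ± 3.51 CPM), Ung, which removes uracil from DNA (2.02 ± 0.276 to 18.5 ± 3.99), and the replication licensing gene Cdt1 (2.86 ± 0.342 to 25.5 ± 4.65). Next were Mthfd2 (7.75 ± 0.542 to 65.9 ± 20.996) and Slc7a1, a transporter of cationic amino acids (17.5 ± 1.27 to 138 ± 57.5). Both were highest in Atf4 replicate 5, with 99.6 CPM of Mthfd2 (45.4 to 69.2 in the other Atf4 libraries) and 231 CPM of Slc7a1 (84.0 to 150). Olfr618, uncertain as above, rose to 19.6 ± 3.20 CPM. By the naming rule, the largest falls were those of the immediate early genes Egr3, Egr2, Nr4a1, Fos and Egr4 and of Miat (49.9 ± 4.49 to 2.18 ± 0.707 CPM). Each of these changes had an edgeR adjusted p of at most 3.3e-05.

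The immediate early and AP-1 list fell in the Atf4 line. It had a median log2 fold change of -1.81, 14 members fell and 1, Batf3, rose by 2.59 ± 0.23 SE (camera adjusted p = 0.00156, adjusted p = 0.433 with an estimated correlation). Egr3 had a log2 fold change of -6.01 ± 0.70 SE, Egr2 of -4.61 ± 0.48 SE, Nr4a1 of -4.32 ± 0.51 SE, Fos of -3.87 ± 0.51 SE and Egr4 of -3.73 ± 0.61 SE. The control libraries were uneven in these genes. Fos was at 20.7, 108, 53.9, 239 and 256 CPM in control replicates 1 to 5. It was at 7.17 to 12.9 CPM in the Atf4 libraries and 31.4 to 67.8 CPM in the Atf3 libraries. Without control replicates 4 and 5, left out after seeing the data, the falls were -4.56, -3.75, -3.08, -2.73 and -2.02 in the same order, and the list median was -1.09 (camera adjusted p = 7.8e-04, and 3.0e-07 to 0.433 over all camera tests).

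Most genes of amino acid supply also rose in the Atf4 line, with smaller list medians than in the Atf3 line. Of 14 amino acid and one-carbon synthesis enzymes 13 rose and 1 fell (camera adjusted p = 9.0e-14, adjusted p = 0.0589 with an estimated correlation). Asns rose by 1.65 ± 0.07 SE and Shmt2, a mitochondrial serine enzyme, by 1.05 ± 0.05 SE, with Gpt2 again lower (-0.29 ± 0.05 SE). Of 12 amino acid transporters 10 rose and 2 fell (camera adjusted p = 2.4e-05, adjusted p = 0.198 with an estimated correlation). Slc6a9 rose by 1.47 ± 0.08 SE and the leucine transporter gene Slc7a5 by 1.02 ± 0.05 SE. The aminoacyl-tRNA synthetases had a median of 0.99 (camera adjusted p = 1.0e-15, adjusted p = 0.114 with an estimated correlation). Mars had a log2 fold change of 1.52 ± 0.08 SE and Gars of 1.33 ± 0.07 SE. Of 16 effectors of the integrated stress response 12 rose and 2 fell (camera adjusted p = 2.0e-05, adjusted p = 0.165 with an estimated correlation). Trib3 rose to 4.46 ± 2.66 CPM, with 9.09 CPM in Atf4 replicate 5 and 2.66 to 3.96 CPM in the other Atf4 libraries. Eif4ebp1 rose by 1.75 ± 0.09 SE and Atf5 by 0.89 ± 0.05 SE. Ppp1r15a, a regulator of eIF2 alpha dephosphorylation, fell (-0.67 ± 0.10 SE). Ddit3 was at 11.9 ± 1.32 CPM in the control line and 11.2 ± 1.01 CPM in the Atf4 line (edgeR adjusted p = 0.325). Endoplasmic reticulum chaperones rose in 15 of 18 cases (camera adjusted p = 4.8e-05, adjusted p = 0.114 with an estimated correlation). Hspa5 rose by 0.57 ± 0.04 SE and Hyou1 by 0.45 ± 0.03 SE. Of 12 cytosolic heat shock proteins 6 rose and 1 fell (camera adjusted p = 0.00630, adjusted p = 0.0612 with an estimated correlation). The mitochondrial chaperone gene Hspd1 rose by 0.89 ± 0.05 SE.

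The S phase list had a median of 1.93 in the Atf4 line (camera adjusted p = 7.5e-59, adjusted p = 0.00602 with an estimated correlation). Mcm5 had a log2 fold change of 2.07 ± 0.06 SE and the histone mRNA-binding gene Slbp of 1.11 ± 0.04 SE. Of 16 G2 and M phase genes 13 rose (camera adjusted p = 3.4e-07, adjusted p = 0.165 with an estimated correlation). Aurkb rose by 1.18 ± 0.06 SE, and Mki67 was at 307 ± 26.7 and 338 ± 48.2 CPM (edgeR adjusted p = 0.213). All 17 cholesterol synthesis genes rose, by a median of 0.68 (camera adjusted p = 2.0e-05, adjusted p = 0.398 with an estimated correlation). Antioxidant and glutathione genes rose in 10 of 12 cases (camera adjusted p = 7.7e-06, adjusted p = 0.0380 with an estimated correlation). Gsr rose by 0.90 ± 0.04 SE and Gclc by 0.71 ± 0.04 SE. Of 12 glycolysis genes 10 rose and 2 fell (camera adjusted p = 0.00156, adjusted p = 0.198 with an estimated correlation). Ldha had a log2 fold change of 0.88 ± 0.04 SE. Of 13 p53 target genes 9 rose and 3 fell (camera adjusted p = 0.00339, adjusted p = 0.114 with an estimated correlation). Cdkn1a had a log2 fold change of 0.98 ± 0.04 SE and Btg2 of -1.28 ± 0.17 SE. MAPK feedback genes rose in 5 of 12 cases and fell in 3 (camera adjusted p = 0.471), with Etv4 at 1.61 ± 0.10 SE and Dusp5 at -1.34 ± 0.13 SE.

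Oligodendrocyte lineage markers fell in 10 of 11 cases in the Atf4 line (camera adjusted p = 0.00102, adjusted p = 0.189 with an estimated correlation). Cnp, an enzyme of myelin, fell by 1.42 on the log2 scale. Of 19 proneural and early neuronal markers 5 rose and 9 fell (camera adjusted p = 0.0281, adjusted p = 0.168 with an estimated correlation). This list call ended with no filter on low counts (0.0547) or with the filter at 1 CPM (0.0644), and over all camera tests its adjusted p was 0.0200 to 0.168. Myt1, Dcx and Tubb3 fell (-2.61 ± 0.14 SE, -1.45 ± 0.16 SE and -0.99 ± 0.10 SE). Of 13 Notch pathway genes 1 rose and 8 fell (camera adjusted p = 0.0170, adjusted p = 0.156 with an estimated correlation). The receptor gene Notch3 rose (0.67 ± 0.06 SE) and Hes1 fell (-1.08 ± 0.13 SE). Mitochondrially encoded genes fell in 9 of 13 cases (camera adjusted p = 0.0236, adjusted p = 0.556 with an estimated correlation). The gene mt-Co1 fell by 0.37 on the log2 scale, and the mitochondrial share of counts was 3.42 ± 0.126%, against 4.07 ± 0.0611% in the control line. Autophagy and lysosome genes rose in 2 and fell in 8 of 13 cases (camera adjusted p = 0.0202, adjusted p = 0.433 with an estimated correlation). Map1lc3b had a log2 fold change of -0.62 ± 0.06 SE.

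The other lists did not pass in the Atf4 line (camera adjusted p-values in brackets). Of 16 neural stem and precursor cell markers 6 rose and 7 fell (0.639). The glutamate transporter gene Slc1a3, Fabp7 and Nes rose (0.84 ± 0.06 SE, 0.70 ± 0.05 SE and 0.33 ± 0.07 SE), Id4 and Id3 fell (-1.59 ± 0.13 SE and -0.85 ± 0.08 SE), and Sox2 was at 228 ± 7.51 and 233 ± 11.4 CPM (edgeR adjusted p = 0.523). Of 11 astrocyte markers 4 rose and 6 fell (0.113), with Gfap at -0.98 ± 0.06 SE and S100b at -1.26 ± 0.09 SE. Interferon-stimulated genes rose in 2 and fell in 4 of 11 cases (0.356), with Rsad2 at -1.41 ± 0.13 SE. The other counts were 3 rising and 4 falling of 10 axon growth genes (0.639) and 3 and 3 of 7 inflammatory signalling genes (0.746). They were 2 and 1 of 5 endothelial markers (0.353; Kdr at 16.4 ± 1.60 CPM), 1 and 1 of 5 ependymal markers (0.838) and 1 and 1 of 2 tested microglia markers. Further, 2 of 3 tested mural cell and fibroblast markers fell. Median, mean and test differed in sign for the inflammatory list (median -0.25, mean 0.24, camera downward), the endothelial list (0.02, -0.02, downward) and the ependymal list (-0.10, 0.01, downward). The endothelial median was -0.146 without Atf4 replicate 5 and 0.114 without Atf4 replicate 2. Counts adjusted over the list alone were identical for all 28 lists except the Notch pathway genes (1 rose, 10 fell).

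In the Atf4 line 5821 genes were higher and 5425 lower than in the control line, 11246 of 18244 (61.6%; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p under 0.05). With a change of at least 2-fold 765 were higher and 882 lower, but 500 and 426 with the filter at 1 CPM, and 331 and 122 among genes at a mean of 10 CPM or more. The libraries of the lines did not overlap in 8733 genes (47.9%, against 0.79% by chance). Of the 26 lists tested 18 passed with the preset correlation, and the S phase and antioxidant lists passed with an estimated one.

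**Figure D3:**
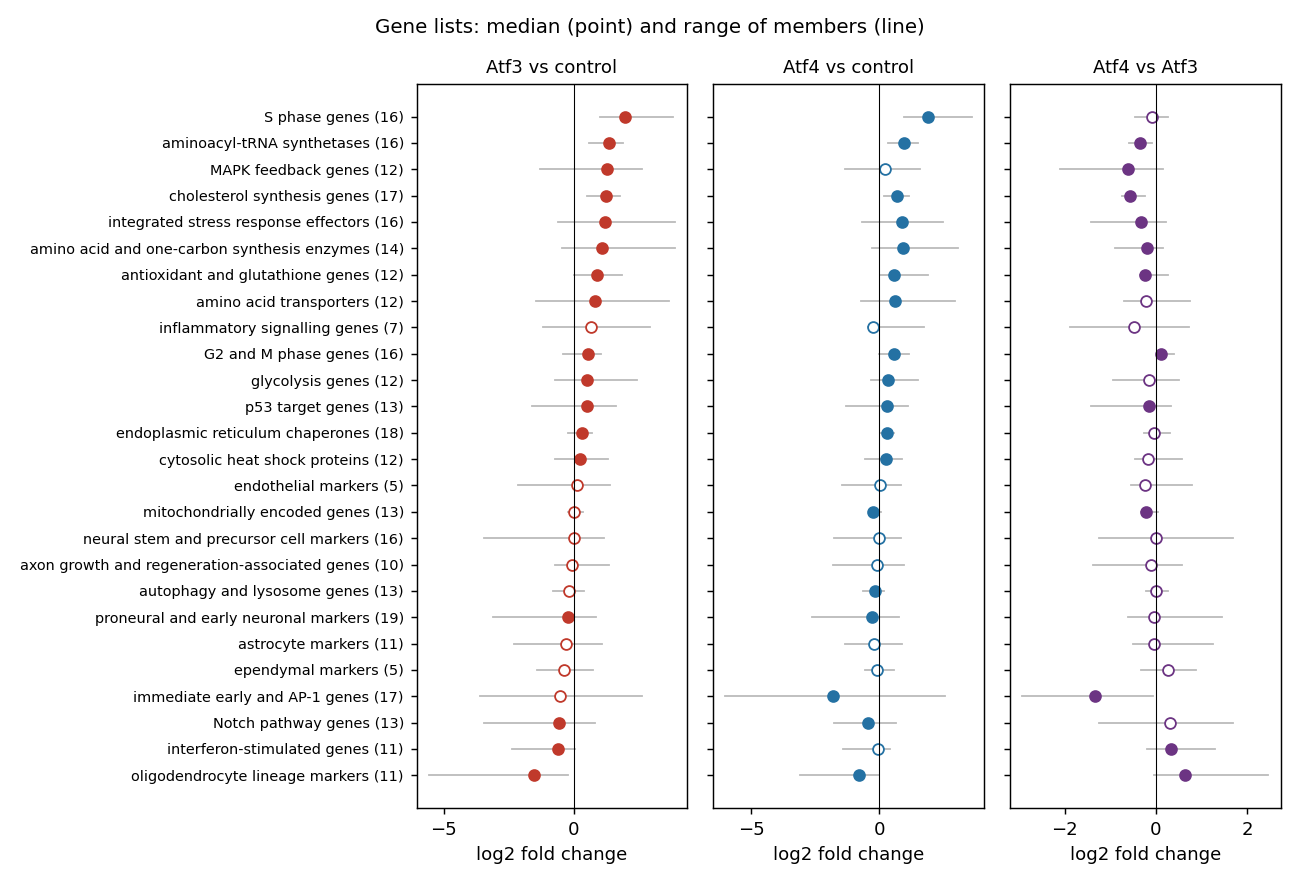
Median log2 fold change (points) and range over members (lines) of the 26 tested gene lists in the 3 comparisons, with the number of tested members in brackets; filled points passed camera with the preset correlation at an adjusted p under 0.05. The S phase list has medians of 2.00 and 1.93 against control and -0.07 between the overexpressing lines.

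The Atf4 line was then compared with the Atf3 line directly. Atf4 mRNA was itself higher in the Atf3 line (at least 227 CPM, against at most 188 CPM in the Atf4 line). The comparison therefore does not set one factor alone against the other. Scg2, Fbxo32 and Miat, which had fallen in the Atf3 line, were higher in the Atf4 line (2.50 ± 0.16 SE, 1.66 ± 0.17 SE and 1.49 ± 0.21 SE), and so was the cholesterol exporter gene Abca1 (1.70 ± 0.10 SE). The melanocortin receptor gene Mc5r and the transporter gene Abca13 rose as well (1.48 ± 0.17 SE and 1.48 ± 0.19 SE). Scg2 and Miat were nonetheless far below their control levels in the Atf4 line too. Scg2 stood at 4.94 to 8.77 CPM in the Atf4 libraries and 1.00 to 1.53 CPM in the Atf3 libraries. By the naming rule, the largest falls besides Atf3 were those of Egr3, Egr2, Nampt, an enzyme of NAD synthesis (189 ± 9.21 to 38.3 ± 3.38 CPM), Junb and Egr1. Egr3 (-2.93 ± 0.71 SE) lost its call with limma-voom (adjusted p = 0.127, the highest of all alternatives, with 5.9e-07 the lowest).

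The immediate early and AP-1 list fell by a median of 1.33 on the log2 scale, with 12 of 17 members lower and none higher (camera adjusted p = 4.1e-05, adjusted p = 0.390 with an estimated correlation). Egr2 had a log2 fold change of -2.48 ± 0.47 SE, Junb of -2.30 ± 0.42 SE, Egr1 of -2.29 ± 0.31 SE and Myc of -1.33 ± 0.20 SE. MAPK feedback genes fell in 11 of 12 cases (camera adjusted p = 8.9e-09, adjusted p = 0.283 with an estimated correlation). Spry2 changed by -1.12 ± 0.12 SE and Etv5 by -0.54 ± 0.06 SE. All 17 cholesterol synthesis genes were lower (camera adjusted p = 7.5e-10, adjusted p = 0.349 with an estimated correlation). Sqle had a log2 fold change of -0.72 ± 0.05 SE and Mvd of -0.66 ± 0.08 SE. Of 16 aminoacyl-tRNA synthetases 13 fell (camera adjusted p = 5.4e-06, adjusted p = 0.390 with an estimated correlation). Rars and Dars changed by -0.58 ± 0.07 SE and -0.34 ± 0.05 SE. Of 16 effectors of the integrated stress response 13 fell (camera adjusted p = 7.9e-04, adjusted p = 0.349 with an estimated correlation). Trib3 had a log2 fold change of -1.42 ± 0.24 SE, Gdf15 of -1.06 ± 0.16 SE and Ddit3 of -0.62 ± 0.07 SE. Of 14 amino acid and one-carbon synthesis enzymes 1 rose and 8 fell (camera adjusted p = 0.00231, adjusted p = 0.390 with an estimated correlation). Cth changed by -0.90 ± 0.11 SE, Psat1 by -0.44 ± 0.03 SE and Asns by -0.36 ± 0.07 SE. Antioxidant and glutathione genes fell in 8 of 12 cases (camera adjusted p = 0.00231, adjusted p = 0.283 with an estimated correlation). Txnrd1 had a log2 fold change of -0.34 ± 0.04 SE and Gclm of -0.25 ± 0.03 SE. The p53 target genes rose in 2 and fell in 7 of 13 cases (camera adjusted p = 0.00459, adjusted p = 0.283 with an estimated correlation). Plk2 had a log2 fold change of -1.42 ± 0.09 SE. Mitochondrially encoded genes fell in 12 of 13 cases (camera adjusted p = 0.00100, adjusted p = 0.450 with an estimated correlation). The genes mt-Nd1 and mt-Nd2 changed by -0.31 ± 0.05 SE and -0.32 ± 0.05 SE, next to mitochondrial shares of 3.42% in the Atf4 line and 3.72% in the Atf3 line. The shares are of plain totals, whereas the fold changes include TMM factors, with means of 1.02 and 0.946 in the same order. Part of the fall in this list thus depends on the scaling, and the list was not tested on plain totals.

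In the Atf4 line against the Atf3 line the lists of oligodendrocyte lineage markers, interferon-stimulated genes and G2 and M phase genes passed the camera test upward. Oligodendrocyte lineage markers rose in 9 of 11 cases (camera adjusted p = 4.5e-04, adjusted p = 0.349 with an estimated correlation). Myrf rose by 0.86 ± 0.09 SE and Cspg4 by 0.63 ± 0.07 SE. Interferon-stimulated genes rose in 5 of 11 cases, with 6 not called (camera adjusted p = 0.00231, adjusted p = 0.349 with an estimated correlation). Irf7 had a log2 fold change of 1.30 ± 0.17 SE and Isg15 of 1.02 ± 0.14 SE. Isg15 was low, at 0.756 CPM in the Atf3 line and 1.53 CPM in the Atf4 line. Low genes tended to rise in this comparison, with medians of 0.21 under 1 CPM, 0.11 at 1 to 10 CPM and -0.05 at 10 CPM or more. Whether the interferon list follows this trend was not tested. G2 and M phase genes rose in 6 of 16 cases, with 10 not called and a median of 0.11 (camera adjusted p = 0.0265, adjusted p = 0.540 with an estimated correlation). Ccnb2 rose by 0.27 ± 0.06 SE and Mki67 by 0.40 ± 0.10 SE. The S phase list, by contrast, had a median of -0.07, with 1 member higher and 2 lower (camera adjusted p = 0.582), Tyms at 0.26 ± 0.04 SE and Ung at -0.45 ± 0.11 SE. Of 19 proneural and early neuronal markers 6 rose and 4 fell (camera adjusted p = 0.258). Tubb3 and Prox1 were higher (1.46 ± 0.10 SE and 0.56 ± 0.07 SE), and Dcx was lower (-0.51 ± 0.18 SE, edgeR adjusted p = 0.0257). The Dcx call ended with DESeq2 (adjusted p = 0.0513), with no filter on low counts (0.0765), with the replicate number as a block (0.0518), with the 10 libraries alone (0.0554) and without Atf3 replicate 3 or 5 or Atf4 replicate 2 or 5 (0.0638, 0.0875, 0.0617 and 0.0502). Over all alternatives its adjusted p was 0.00936 to 0.0875.

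The other lists did not pass in this comparison (camera adjusted p-values in brackets). Of 13 Notch pathway genes 7 rose and 4 fell (0.529), with Hes5 at 1.69 ± 0.27 SE, Hes1 at -1.24 ± 0.13 SE and Jag1 at -1.01 ± 0.07 SE. Of 16 precursor markers 5 rose and 7 fell (0.317), with Fabp7 at -0.48 ± 0.05 SE, Nes at -0.29 ± 0.07 SE and Sox2 at 0.06 ± 0.04 SE (edgeR adjusted p = 0.291). Of 11 astrocyte markers 3 rose and 3 fell (0.953), Apoe by 1.25 ± 0.12 SE and Gfap by 0.27 ± 0.06 SE. Amino acid transporters rose in 3 and fell in 6 of 12 cases (0.258, but 0.00352 without Atf4 replicate 5 and up to 0.715 over all camera tests), with Slc7a5 at 0.28 ± 0.05 SE. The counts were 4 rising and 8 falling of 18 endoplasmic reticulum chaperones (0.529) and 4 and 7 of 12 cytosolic heat shock proteins (0.128, 0.0183 with no filter on low counts and up to 0.349 over all camera tests). They were 3 and 6 of 12 glycolysis genes (0.151, 0.0128 with no filter and up to 0.540 over all camera tests), 3 and 3 of 13 autophagy and lysosome genes (0.953) and 1 and 3 of 10 axon growth genes (0.218, 0.0122 with the 10 libraries alone and up to 0.450 over all camera tests). For 7 inflammatory signalling genes they were 2 and 4 (0.181), with Socs3 at -1.33 ± 0.15 SE. Of 5 endothelial markers 2 rose and 1 fell (0.464), with Kdr at 0.70 ± 0.08 SE, and 2 of 5 ependymal markers rose (0.181). Of 2 tested microglia markers 1 fell, and of 3 mural cell and fibroblast markers 1 rose and 1 fell. Median, mean and test differed in sign for the precursor list (median 0.01, mean -0.05, camera downward) and the neuronal list (-0.05, 0.06, upward). They also differed for the astrocyte list (-0.04, 0.05, upward), the endothelial list (-0.25, 0.07, upward) and the autophagy list, whose median and mean were both within 0.01 of 0.

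Adjusted over the list alone, the counts differed for 9 of the 28 lists between the overexpressing lines: amino acid synthesis (1 rose, 9 fell), integrated stress response (2 and 13), heat shock (4 and 8), immediate early (0 and 15), precursor (6 and 7), neuronal (7 and 4), S phase (1 and 1), glycolysis (3 and 8) and inflammatory genes (3 and 4). In all, 3595 genes were higher and 4363 lower in the Atf4 line than in the Atf3 line, 7958 of 18244 (43.6%; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p under 0.05), and with a change of at least 2-fold 422 were higher and 174 lower, but 16 and 44 among the 9952 genes at a mean of 10 CPM or more. The libraries did not overlap in 4715 genes (25.8%, against 0.79% by chance). Of the 26 lists 12 passed with the preset correlation and 0 with an estimated one (fry: 21). Atf4 replicate 5 lay closer to the Atf3 line in several of these genes: it had 188 CPM of Atf4 (128 to 154 in the other Atf4 libraries, 227 to 267 in the Atf3 line), 99.6 CPM of Mthfd2 (45.4 to 69.2 and 98.8 to 125) and 1.45 CPM of Hes5 (3.03 to 5.05 and 0.633 to 1.60).

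**Figure D4:**
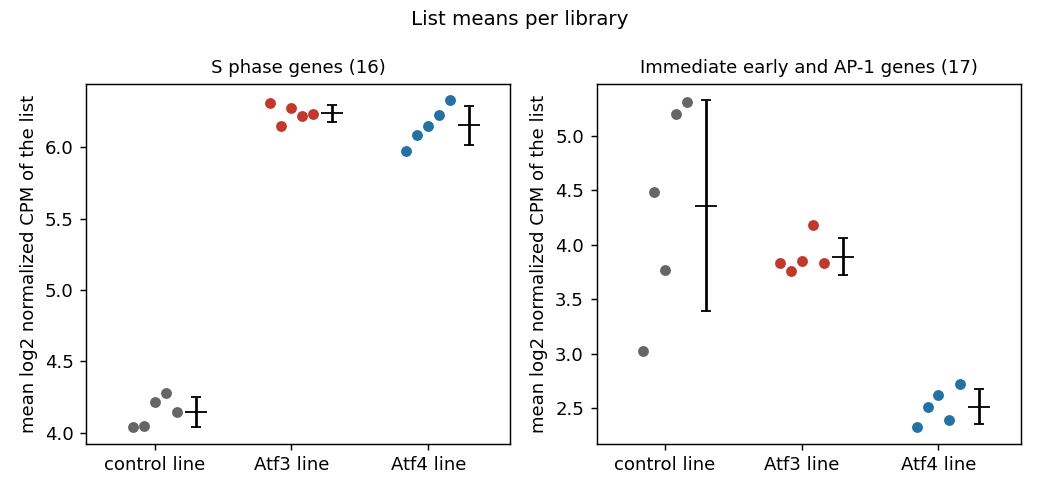
Mean log2 CPM of the 16 S phase genes (left) and of the 17 immediate early and AP-1 genes (right) in each library, grouped by line; bars give the mean and SD of 5 libraries. S phase means are 4.04 to 4.28 in the control libraries, 6.15 to 6.31 in the Atf3 libraries and 5.98 to 6.33 in the Atf4 libraries, and immediate early means are 3.03 to 5.31, 3.75 to 4.18 and 2.32 to 2.72.

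The responses of both lines were finally set against each other. Called in both lines against control, 5262 genes were higher in both and 4780 lower in both, and 133 moved in opposite directions. Genes such as Cdc6, Mthfd2, Asns, Gars and Eif4ebp1 rose in both lines, and Miat, Myt1, Id4, Gfap and Kdr fell in both. Of 3387 genes changed at least 2-fold in either line, transgenes left out, 2937 (86.7%) had a smaller log2 fold change in the Atf4 line, disregarding sign. Of the 1646 that changed at least 2-fold in the Atf4 line, 450 (27.3%) were smaller in the Atf3 line. Both counts were chosen after seeing the data. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.88 and a covariance of 0.459. Both comparisons use the same 5 control libraries. Simulated unchanged groups set against such controls gave a mean of 0.05 genes called in one direction in both (1 at most in 20 simulations), a correlation of 0.492 and a covariance of 0.0118. The covariance difference was 0.447. Independent lists of these sizes would share 2144 higher and 1971 lower genes. With the controls split between the comparisons, 8231 to 8980 genes were called in the same direction over 20 splits and 60 to 169 in opposite directions. Correlations were 0.768 to 0.831, with a mean covariance of 0.502. The split fits tested 19362 genes in place of 18244, and each comparison had only a part of the controls. Their values therefore differ from the observed ones in more than the sharing of controls. Both parts of the controls come from the single control line. Neither splits nor simulations can therefore tell a response shared by both overexpressing lines from a difference of that control line.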

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

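The tests of the Atf4 level and of the immediate early genes, the test at equal depth, the gaps on plain CPM, and the fits without control replicates 4 and 5 were chosen only after the results were seen. Among 324 sets of 5 libraries (108 named genes in 3 lines) and 15 sets of library measures, 12 had a library far from the other 4, with a gap of more than 0.71 of the whole range, and chance gives about 1 in 20. Gaps of genes were taken on log2 CPM and those of library measures on the values themselves. In the Atf4 line Psat1 was low in replicate 2 (586 CPM against 614 to 624; gap 0.742 of the range), Slc38a1 high in replicate 1 (2.15 against 1.42 to 1.53; 0.818), Aurkb low in replicate 5 (73.8 against 76.3 to 77.4; 0.7103) and Plk2 high in replicate 5 (122 against 91.5 to 98.3; 0.752). In the Atf3 line Cspg4 was low in replicate 1 (11.4 CPM against 13.5 to 14.5; 0.7145), Notch3 high in replicate 5 (11.4 against 9.14 to 9.60; 0.781), and the mitochondrial share of counts low in replicate 4 (3.23% against 3.77 to 3.95%; 0.7498). In the control line Slc6a9 was high in replicate 1 (8.03 CPM against 7.09 to 7.30; 0.771), Cdt1 high in replicate 3 (3.46 against 2.65 to 2.79; 0.809), Tyms high in replicate 4 (22.8 against 20.0 to 20.5; 0.8096), Slc7a5 low in replicate 2 (461 against 487 to 497; 0.7144) and Irf7 low in replicate 5 (2.52 against 2.71 to 2.78; 0.769). On plain CPM 8 of the 11 gene sets stayed over 0.71, Aurkb (0.705), Cspg4 (0.69) and Slc7a5 (0.707) did not, and 4 others passed: Trib3 and Spry2, high in Atf4 replicate 5 (0.797 and 0.723), and Egr3 and Junb in Atf3 replicate 4 (0.769 and 0.731).

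The number of genes called was compared with other splits of the same 10 libraries, 100 per comparison, the real split included. For Atf3 against control 1 of the 100 splits reached 13351 genes, the real one, and the highest other gave 0. For Atf4 against control 1 of 100 reached 11246 genes and the highest other gave 2867. For Atf4 against Atf3 1 of 100 reached 7958 genes and the highest other gave 4613. In the same order 99, 97 and 90 of the other splits gave 0 genes. Every other split mixes libraries of both lines, which lie apart, and so widens the spread within its groups. These counts therefore show that libraries group by line, and they cannot tell whether the lines differ by chance. The 4 other splits with the most genes in the last comparison (4613, 4191, 2915 and 1136) all moved Atf4 replicate 5 to the Atf3 side, which points to a structure of the samples. For the lists, 1 of 100 splits reached the 17 lists of Atf3 against control (highest other 15) and 1 of 100 the 18 lists of Atf4 against control (highest other 16). For Atf4 against Atf3, 14 of 100 reached the 12 lists (highest other 14). Against control, mixed splits that called 0 genes still passed up to 15 and 16 lists. As with the genes, none of these 3 counts of lists can tell whether the lines differ by chance. For the genes changed in one direction in both lines, 1 of 100 regroupings of the 15 libraries reached 10042, and the highest other gave 5237.

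Atf4 mRNA was higher in the Atf3 line (250.4 ± 16.5 CPM) than in the Atf4 line (153 ± 21.7 CPM). Exchanged libraries are argued against, since the lowest Atf3 level in the Atf3 line was 161 times the highest in the other 10 libraries. Library scaling is argued against too: the ratio of mean Atf4 levels was 1.63 with TMM, 1.63 with RLE and 1.52 with plain totals. What stays open is that transcripts of the Atf4 transgene were missed or cannot be told apart from endogenous ones in counts per gene, next to a ratio of 1.84 between the Atf4 line and the control line. An effect of Atf3 on the endogenous Atf4 gene is a biological explanation that the design names and that was not tested.

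S phase genes were higher in both overexpressing lines than in the control line, by medians of 2.00 and 1.93. Depth is argued against, because in all 16 pairs of an overexpressing and a control library with totals within 5% of each other the mean log2 CPM of the list differed by at least 1.70, against a range of at most 0.355 within a line. Thinning to 53.7 M counts (lower median 1.93) decides nothing, since mean totals were alike beforehand (59.5, 59.5 and 60.4 M). Gene length and GC content are argued against as well: of 10000 lists of genes matched on expression, length and GC content, 0 reached the median in either line, and the highest gave 0.80 and 0.52. A difference of the single control line that has nothing to do with the transgenes (lines with a transgene differed by a median of only -0.0737) and an effect of both transcription factors, the biological explanation, cannot be told apart with 1 line per construct.

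Immediate early genes were lower in the Atf4 line, by a median of -1.81 against control. Unevenness among the control libraries is argued against as the whole cause, because the list was also lower than in the Atf3 line (median -1.33, camera adjusted p = 4.1e-05, adjusted p = 0.39 with an estimated correlation). These fold changes do not use the controls, but the test came from the fit to all 15 libraries, where controls enter the spread. With the 10 libraries of both overexpressing lines alone, 15 members of the list were called lower. A difference in handling at harvest could still move these genes, since they respond within minutes. Fos differed 12.3-fold between the highest and the lowest control library, and no handling times are given in the sources used here. An effect of Atf4 is the biological explanation that the design names and cannot be told apart from handling here.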

How the results depend on the processing

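Leaving out control replicates 4 and 5 together and thinning all libraries to 1 depth were chosen only after seeing the data. All other alternatives in this section were planned. Of 3231 alternative values of 173 named gene results, 16 changed the call or the sign, in 6 results, while the others kept both. Most named genes were chosen from these same data, for large changes without overlap or for the smallest adjusted p in their list. Their calls were thus likely to hold in refits of the same libraries, so these counts do not measure how stable other genes are. Sign changes fell on genes near 0 that were not called. Sox2 in the Atf3 line, -0.02 as reported, was 0.0043 with no filter and lay between -0.0546 (without control replicate 2) and 0.0066 (without Atf3 replicate 5) with 1 library left out. Sox2 in the Atf4 line, 0.03 as reported, was -0.00064 with the filter at 1 CPM. Ddit3 in the Atf4 line, -0.09 as reported, was 0.0163 without control replicates 4 and 5. For all of these the cause was not tested.

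The fold threshold of 2 left 3190, 1647 and 596 genes of the 13351, 11246 and 7958 called for Atf3 against control, Atf4 against control and Atf4 against Atf3, by its construction. Those counts became 1874, 926 and 224 with the filter at 1 CPM, which tests fewer genes, and 4792 for Atf3 against control with no filter. Camera with an estimated correlation passed 2, 2 and 0 lists where the preset correlation passed 17, 18 and 12, and fry passed 21 for Atf4 against Atf3; the cause was not tested. DESeq2 called 14273, 11466 and 8007 genes, and limma-voom 13357, 11295 and 7944. Leaving out 1 library gave 13028 to 13347, 10746 to 11287 and 7157 to 8427 genes, 3223 to 3447, 1634 to 1865 and 580 to 752 with at least a 2-fold change, and 14 to 18, 18 and 12 to 13 lists. The count of genes changed in one direction in both lines was 9617 to 10059. Without Atf4 replicate 5 the Atf4 and Atf3 lines differed in 8427 genes. Without control replicates 4 and 5 the counts against control were 12892 and 10391 genes and 14 and 18 lists, with 9380 shared.

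Replicate numbers did not pair the libraries: the 15 correlations of deviations between libraries of one number were -0.114 to 0.124, 1 was over 0.1, and 0 of 15 libraries correlated best with its own number. Libraries of different lines and different numbers correlated at -0.258 to 0.330, the highest being Atf3 replicate 3 with Atf4 replicate 5. Whether libraries of different lines share a structure that the labels do not give was not tested. With the number as a replicate block 13132, 10968 and 7589 genes, 17, 18 and 12 lists and 9812 shared genes were called. The libraries held 53.7 to 69.6 M counts, and after thinning to 53.7 M counts 13204, 11114 and 7852 genes were called.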

Other observations

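The test of receptor genes was planned before its result was seen, and the genes named by direction were chosen only after their values were seen. Genes that moved in opposite directions in both lines were few and mostly small in size: 76 were higher in the Atf3 line and lower in the Atf4 line, and 57 the reverse. Among those with a mean log2 CPM of at least 2, only 3 had a change of at least 0.5 on the log2 scale in both lines, Atf3 itself, Klf6 and Camk2n1. Klf6, a transcription factor gene, was at 38.9 ± 13.5 CPM in the control line, 63.4 ± 7.30 in the Atf3 line and 24.6 ± 5.26 in the Atf4 line (log2 fold changes 0.70 ± 0.18 and -0.67 ± 0.19 SE, edgeR adjusted p = 0.00211 and 0.00481). Camk2n1, which encodes an inhibitor of the kinase CaMKII, was at 48.3 ± 4.43, 72.6 ± 4.97 and 28.7 ± 2.46 CPM (0.59 ± 0.07 and -0.75 ± 0.07 SE, edgeR adjusted p = 2.0e-07 and 2.0e-08). The MAPK feedback gene Spry2 was among the 133 as well, at 132 ± 25.4, 229 ± 19.2 and 105 ± 15.6 CPM (0.79 ± 0.11 and -0.33 ± 0.11 SE, edgeR adjusted p = 5.0e-06 and 0.0168), and so was the interferon-stimulated gene Isg15, in the other direction, at 1.15 ± 0.112, 0.756 ± 0.108 and 1.53 ± 0.228 CPM.

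Falls of at least 2-fold were mostly those of low genes. Of 4587 tested genes with a mean under 1 CPM, 347 were at least 2-fold higher and 1101 lower in the Atf3 line than in the control line, with a median log2 fold change of -0.41. Of 9952 genes at 10 CPM or more, 672 were higher and 313 lower, with a median of 0.12. In the Atf4 line the numbers were 245 and 543 among the low genes and 331 and 122 among the abundant genes. Between the Atf4 and the Atf3 line 323 low genes were higher and 95 lower in the Atf4 line, and 16 and 44 of the abundant genes.

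A hypothesis was that the control line held more background reads, from genomic DNA or unspliced RNA, since fewer genes had any count in the other lines (exact permutation test, two-sided, p = 0.00794 for each pair of lines, the smallest that 5 against 5 allows, adjusted p = 0.0159). Background reads should then raise olfactory and vomeronasal receptor genes, most of which are silent outside sensory tissue. The summed level of 1968 such genes, Olfr618 left out, was 98.3 ± 2.97 CPM in the control line, 103.5 ± 5.44 in the Atf3 line and 101.6 ± 3.34 in the Atf4 line (exact permutation test, two-sided, p = 0.119 and 0.135 against control and 0.508 between the overexpressing lines, adjusted p = 0.162, 0.162 and 0.508). These sums were divided by plain library totals, without TMM factors. The factors averaged 1.04 in the control line, 0.946 in the Atf3 line and 1.02 in the Atf4 line. With them both overexpressing lines would stand higher still against control, so the p-values hold for plain totals only. The ratio of the Atf3 line to the control line was 1.05 on plain totals, so a higher background in the control line was not seen in these genes.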
